A study of Mus musculus with 9 samples.

How the data were processed

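Gene expression of innate lymphoid cells (ILCs) from mouse skin was measured on 9 Affymetrix one-colour arrays, one per sorted sample. Per the labels, the cells came from female B6 mice carrying EGFP at one Ccr10 allele, so that green fluorescence reports CCR10 expression. They were sorted as CD45.2-positive, CD3-negative and lineage-negative cells, as a GFP-positive and a GFP-negative fraction, straight into Trizol. The exclusion panel in the labels names CD3, CD5, CD11b, B220, the 7-4 antigen, Gr-1 and a Ter antigen, and no mast cell marker. Mice with intact Rag1 (called Rag1-sufficient here) gave 2 GFP+ and 2 GFP- samples, and Rag1-/- mice gave 2 GFP+ and 3 GFP- samples. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

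The authors deposited 1 intensity per probe set and array, on a linear scale, with 24922 probe sets and no detection calls. Per the labels, biotinylated single-stranded DNA was hybridised, and the submitters' processing notes name MAS5 without a version or a role. The normalization between arrays and the genome build were not given in the sources used here. The deposited values had already been brought to a common scale: the array medians ran from 74.1 to 77.6, a range of 0.065 on the log2 scale. In 12464 probe sets (50.0%) at least 2 arrays held exactly the same value. Among the tested probe sets, those with equal values on every array of a group numbered 722 in Rag1-sufficient GFP+, 686 in Rag1-sufficient GFP-, 451 in Rag1-/- GFP+ and 103 in Rag1-/- GFP- samples, so that the spread within groups of 2 arrays is partly understated. The number of arrays limits the precision of every value given here.

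Gene names came from the array's platform annotation: 21425 probe sets had 1 gene symbol, 1399 had several and 2098 had none. By gene identifier, 21347 of the named sets matched the mouse reference GRCm38.p6, which was used for current symbols and gene order only. Probe sets with several symbols or none were counted and not named. Where a gene had several probe sets, that with the highest mean over all arrays stood for it, and Il1rl1, Il22 and Areg were not analysed here.

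Intensities were used as deposited and transformed as log2(value + 1), which understates the change of dim genes. The 30% of probe sets with the lowest mean (below an intensity of about 41.6) were left out, which left 17445 probe sets for 13924 genes. A linear model with 1 mean for each of the 4 groups was fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, 5 residual and 3.56 prior degrees of freedom). Comparisons were drawn from this model, tested two-sided and adjusted by Benjamini-Hochberg over all probe sets, with 0.05 as the threshold. They were GFP+ against GFP- within each genotype, Rag1-/- against Rag1-sufficient within each fraction, the mean of each pair and the interaction. Differences are given on the log2 scale as estimate ± SE, and levels as mean intensity ± SD.

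Gene lists, 29 in all, were fixed before the data were examined, as were the comparisons, the alternative settings and the rule for the genes named. They cover ILC2, ILC3, NK and ILC1, pan-ILC, migration, MHC class II, MHC class I, interferon response, immediate early, NF-kB, cell cycle, receptor, glycolysis, oxidative phosphorylation, cholesterol synthesis and fatty acid genes. The others hold markers of T, B and plasma, mast, basophil and eosinophil, macrophage and monocyte, dendritic and Langerhans, neutrophil, keratinocyte, fibroblast, endothelial, melanocyte and Schwann, adipocyte and muscle, and erythroid cells. The 26 lists with at least 4 measured genes were tested against all other genes with camera at a preset correlation of 0.01. Those calls were set beside camera with an estimated correlation and beside fry, which asks whether a list's genes move one way on balance. The basophil and eosinophil list (2 genes measured), the neutrophil list (3) and the erythroid list (2) were too short to test. In every list call the median, the mean and the test shared a sign.

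The genes named were those with the 10 largest increases and the 10 largest decreases past the threshold in each comparison, or the 5 with the smallest p where none passed. To these were added the 2 to 4 leading members of each list with a camera call, and a fixed panel of lineage, cytokine and marker genes that included Ccr10, Rag1, Rag2, Gata3, Tbx21, Eomes, Il7r, Id2, Il5, Il13, Il17a, Ifng, H2-Ab1, Cd3e, Cpa3, Krt14, Col1a1 and Lyz2. Predicted genes and Riken clones were counted but not named.

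The model was tested on simulated data (17445 probe sets, 200 of them changed per run, 5 runs). These had the real means and normal noise with the spread fitted by the model, the same in all groups and without tied values. Changes of 1 on the log2 scale were recovered at 80.4% for GFP+ against GFP- in Rag1-sufficient mice. For Rag1-/- against Rag1-sufficient the recovery was 81.8% in GFP+ and 84.8% in GFP- cells. It was 97.2% for the gate effect averaged over genotypes and 95.8% for the genotype effect averaged over fractions. False calls made up 4.31% to 6.11% of the calls. The real arrays held tied values and differed in estimated precision (array weights 0.463 to 2.01), so both rates may be worse there. In simulated lists of 20 genes camera called 20 of 20 lists shifted by 0.5, and 1 of 200 unshifted lists. The simulated genes varied independently of one another, so this rate of false calls does not carry over to lists of co-expressed genes.

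The alternative settings were no filter, a filter at 50%, quantile normalization, a pseudocount of 32, the replicate number as a block, a fit on only the groups compared, array weights, and leaving out each array in turn. Principal components, gene order around Rag1 and other splits of the arrays were computed in the same scripts, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.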

Results

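The series compared skin ILCs that express the chemokine receptor CCR10 with those that do not, in mice with and without Rag1, the recombinase needed for T and B cell receptors. ILCs are lymphocytes without such receptors that respond to tissue cytokines. CCR10 was read from a fluorescent reporter, and 9 sorted samples were hybridised: 2 GFP+ and 2 GFP- samples from Rag1-sufficient mice, and 2 GFP+ and 3 GFP- samples from Rag1-/- mice. Array medians lay between 74.1 and 77.6 intensity units. Replicates of one group had rank correlations between 0.981 (the 2 Rag1-/- GFP+ arrays) and 0.992 (the 2 Rag1-sufficient GFP+ arrays). Arrays of different groups reached as high, up to 0.993 for Rag1-/- GFP+ replicate 2 with Rag1-/- GFP- replicate 1. Rag1-/- GFP+ replicate 1 was closer to Rag1-sufficient GFP- replicate 1 (0.987) than to its own replicate.

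The targeted gene itself gave no check of the genotype. Rag1 was read at 28.4 to 31.4 and Rag2 at 13.8 to 15.7 intensity units across all 9 arrays, below the expression filter, and the part of Rag1 that its probes cover was not given. Ccr10, the reporter locus, was read at 147 ± 22.9 (n = 2) in GFP+ and 127 ± 2.28 (n = 2) in GFP- cells of Rag1-sufficient mice. In Rag1-/- mice it was read at 122 ± 36.6 (n = 2) and 112 ± 11.6 (n = 3). Its difference between fractions was 0.19 ± 0.20 (adjusted p = 0.801) in Rag1-sufficient and 0.10 ± 0.18 (adjusted p = 0.872) in Rag1-/- mice, so the Ccr10 signal did not separate the sorted fractions beyond the spread between replicates. Without Rag1-/- GFP+ replicate 1 the Rag1-/- difference of Ccr10 was -0.21. The general ILC genes Id2, a regulator of ILC development, and Il7r, the interleukin-7 receptor chain, were bright in all groups. Id2 had group means between 7316 and 7510 and Il7r between 2952 and 3426. Eomes, a transcription factor of NK cells, stayed at 29.4 to 41.8 on every array.

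In Rag1-sufficient mice, sorted CCR10+ cells had more transcript of mitotic genes such as Nusap1 than CCR10- cells. They had less of the mast cell genes Mrgprb1 and Cma1, of Plek and of the cytokine Il1b. The GFP- arrays carried mast cell transcripts, and whether ILCs or other sorted cells account for such differences was not resolved. Nusap1, which organises the mitotic spindle, was at 292 ± 6.73 (n = 2) in GFP+ and 116 ± 10.3 (n = 2) in GFP- cells, a rise of 1.33 ± 0.12 (adjusted p = 0.00843). Plek, a protein kinase C substrate of leukocytes and platelets, was at 66.8 ± 3.98 (n = 2) against 433 ± 54.8 (n = 2), a difference of -2.67 ± 0.17 (adjusted p = 0.00202). In all, 140 probe sets differed, 58 higher and 82 lower in GFP+ cells, and 67 of them by more than 2-fold.

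Several of the 31 named genes that rose in CCR10+ cells act in DNA replication or mitosis. Rfc4, a subunit of the clamp loader at replication forks, rose by 1.79 ± 0.27, and the spindle checkpoint gene Mad2l1 by 1.62 ± 0.22. Ube2c, which drives the degradation of mitotic cyclins, rose by 1.28 and the mitotic kinase Plk1 by 0.85. The core histone genes H2bc14 (1.59), H2ac4 (1.45) and H2bc9 (1.11) and the histone chaperone Asf1b (1.09) rose as well. Histone sets made up 24 of the 58 higher probe sets, and histone genes resemble one another closely enough that their probes may read several members. Genes of other functions rose too, among them Clec12a, an inhibitory lectin receptor, by 1.63. Of the 24 measured cell cycle genes all had a positive difference, with a median of 0.47, and 2 rose, or 11 when adjusted over the list alone (camera adjusted p = 3.41e-12). With an estimated correlation the adjusted p of this list was 0.0935.

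Mast cell genes formed the most strongly reduced group in CCR10+ cells. Of the 11 measured mast cell markers 8 fell, and all 11 when adjusted over the list alone, with a median of -2.05 (camera adjusted p = 6.83e-23, and adjusted p = 0.0854 with an estimated correlation), or of -2.25 without Rag1-sufficient GFP- replicate 2. They included the mast cell receptor Mrgprb1 (-3.46 ± 0.39), the chymase Cma1 (-2.56 ± 0.31), the steroid-synthesis enzyme Cyp11a1 (-2.30 ± 0.28) and the tryptase Tpsb2 (-1.77 ± 0.16, adjusted p = 0.00843). The mast cell protease Cpa3 was at 20.9 ± 0.802 (n = 2) in GFP+ and 4949 ± 23.7 (n = 2) in GFP- cells. The Cpa3 difference of -7.82 ± 1.61 had an adjusted p of 0.0812, because the shared spread of the model includes the 2 Rag1-/- GFP+ arrays, which read 2085 and 19.9. Cpa3, Mrgprb1 and Cyp11a1 in GFP+ cells lay under the filter limit of 41.6 units, so the size of their differences is approximate.

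Single genes of inflammation and some surface receptors fell as well in this comparison. The cytokine Il1b was at 66.7 ± 15.2 (n = 2) in GFP+ and 406 ± 47.1 (n = 2) in GFP- cells, a difference of -2.60 ± 0.31 (adjusted p = 0.0106). The neutrophil attractant Cxcl2 fell as well (-2.32 ± 0.25). Among immunoglobulin-like receptors, Lilr4b was 8.01-fold lower, and the inhibitory Lilrb4a (-2.43) and Pilra (-2.32) fell. The integrin chain Itga4 (-2.42), the orphan receptor Gpr141b (-2.40) and the small nucleolar RNA Snora75 (-3.06) fell too. Of 20 NF-kB and inflammatory genes 2 fell, or 5 when adjusted over the list alone (camera adjusted p = 5.90e-06, and adjusted p = 0.0854 with an estimated correlation). Of 24 immediate early genes, Jun (-1.26) and Fos (-0.92) fell, or 5 when adjusted over the list alone (camera adjusted p = 4.08e-08, and adjusted p = 0.0854 with an estimated correlation).

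Of 21 measured ILC2 genes none passed over all genes in this limma fit, in which 2264 sets had an unadjusted p under 0.05, while 8 fell when adjusted over the list alone. The list had a median of -0.19 (camera adjusted p = 3.95e-05, and adjusted p = 0.0854 with an estimated correlation). The ILC2 receptor Klrg1 differed by -1.11 ± 0.27 (adjusted p = 0.126) and the eosinophil growth factor Il5 by -0.85 ± 0.26 (adjusted p = 0.214). The type 2 cytokine Il13 differed by 0.53 ± 0.19 (adjusted p = 0.287) and the ILC2 regulator Gata3 by -0.57 ± 0.21 (adjusted p = 0.306). For Tbx21, the regulator of type 1 cells, the difference was 0.76 ± 0.32 (adjusted p = 0.366), and for its target Ifng it was 1.37 ± 0.69 (adjusted p = 0.464). Il17a differed by -0.09 ± 0.16 (adjusted p = 0.908), and by 0.11 without Rag1-sufficient GFP+ replicate 2 and 0.08 without GFP- replicate 1.

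Migration genes had a median of 0.16, without a single gene past the threshold and 2 higher when adjusted over the list alone (camera adjusted p = 0.0492, and adjusted p = 0.641 with an estimated correlation). Among them the egress receptor S1pr1 differed by 0.86 ± 0.18 (adjusted p = 0.0915) and the skin-homing receptor Ccr4 by 0.94 ± 0.23 (adjusted p = 0.128). Oxidative phosphorylation genes had a median of 0.24 (camera adjusted p = 0.0186, and adjusted p = 0.687 with an estimated correlation). Without Rag1-sufficient GFP- replicate 2 neither the migration list (camera adjusted p = 0.0853) nor the oxidative phosphorylation list (0.0531) passed. The dendritic cell list, in which Xcr1, a receptor of cross-presenting dendritic cells, fell by 0.78, had a camera adjusted p of 0.00317 (adjusted p = 0.0935 with an estimated correlation).

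The 13 keratinocyte markers had a median of -0.66 (camera adjusted p = 5.93e-05, and adjusted p = 0.456 with an estimated correlation). This rested on Rag1-sufficient GFP- replicate 2, in which the keratin Krt14 read 782 against 375 in replicate 1 and 277 and 300 in the GFP+ arrays, and without it the median was -0.13 (camera adjusted p = 0.199). Endothelial and pericyte markers had a median of -0.24 (camera adjusted p = 0.00777, and adjusted p = 0.343 with an estimated correlation). Fatty acid genes had a median of -0.10 (camera adjusted p = 0.0423, and adjusted p = 0.464 with an estimated correlation) and fibroblast markers one of -0.13 (camera adjusted p = 0.0475, and adjusted p = 0.464 with an estimated correlation). Without that array the fatty acid list (camera adjusted p = 0.289) and the fibroblast list (0.362) did not pass either, nor without Rag1-/- GFP+ replicate 1 (0.0689 and 0.0620). No single gene of these 4 lists passed over all genes. The melanocyte and Schwann cell list (median 0.36, camera adjusted p = 0.158), the interferon response list (0.919), the receptor list (0.284) and the adipocyte and muscle list (0.933) did not pass. The collagen gene Col1a1 differed by -0.11 ± 0.15 (adjusted p = 0.869; 0.03 without replicate 2 of either fraction) and the myeloid lysozyme Lyz2 by -0.73 ± 0.40 (adjusted p = 0.510).

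The count of 140 sets rested on small groups. It was 5 without GFP+ replicate 1, 6 without GFP+ replicate 2, 5 without GFP- replicate 1 and 3 without GFP- replicate 2 of the Rag1-sufficient arrays, which leaves a lone array in its group. It was 333 without replicate 1 and 335 without replicate 2 of the Rag1-/- GFP+ arrays, 68 without Rag1-/- GFP- replicate 2, and 1290 (866 higher and 424 lower) with array weights.

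**Figure D1:**
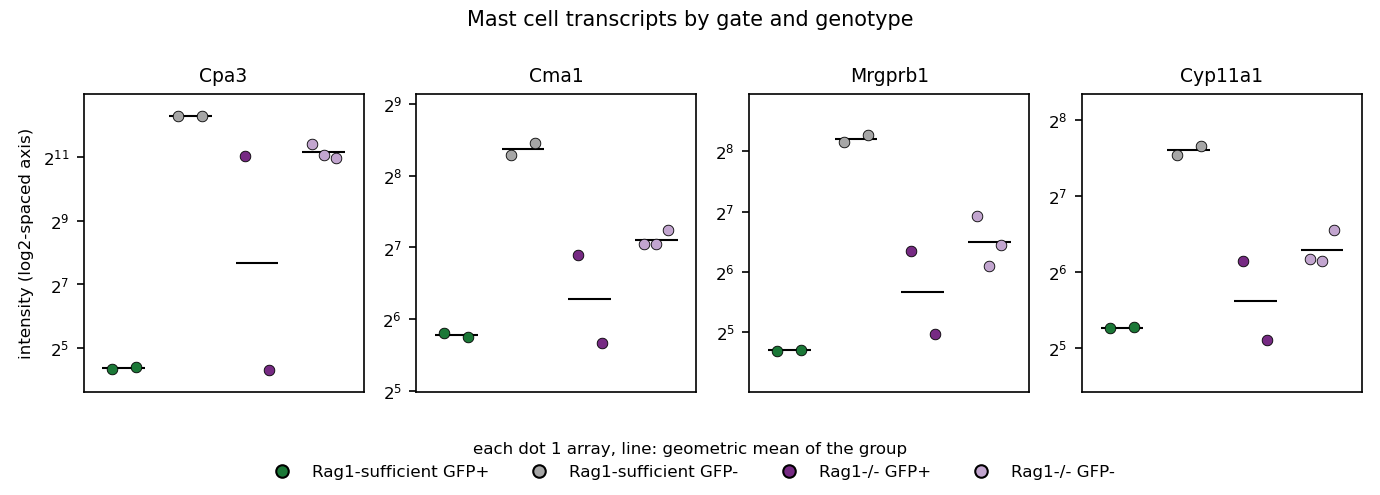
Array intensities (log2-spaced axis) of 4 mast cell transcripts by fraction and genotype, 1 dot per array with a line at the geometric mean of the group. For Cpa3, the Rag1-sufficient GFP- arrays read 4932 and 4965, the Rag1-/- GFP- arrays 2009 to 2686, and the 2 Rag1-/- GFP+ arrays 2085 and 19.9.

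In Rag1-/- mice no single gene passed the threshold between CCR10+ and CCR10- ILCs, a comparison whose power was not simulated. In the limma fit 0 probe sets passed the threshold (smallest adjusted p = 0.688), while 1098 had an unadjusted p under 0.05. The 5 genes with the smallest p differed by -0.77 ± 0.12 for Fam169b, -0.65 ± 0.11 for the polarity gene Pard6g, -0.42 ± 0.07 for Dhx58, a cytosolic RNA sensor, -0.48 ± 0.09 for the cytokine Lif and -0.85 ± 0.15 for the tetraspanin Tspan32. Klrg1 (-1.17 ± 0.25), Il5 (-0.84 ± 0.24) and Tnfrsf4, the costimulatory receptor OX40 (-1.05 ± 0.24), likewise had an adjusted p of 0.688.

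Several gene groups still shifted in Rag1-/- mice under the preset correlation. The 12 glycolysis genes were all lower in GFP+ cells, with a median of -0.39, and 4 fell when adjusted over the list alone (camera adjusted p = 1.10e-06, and adjusted p = 0.357 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.39 (camera adjusted p = 1.36e-05, and adjusted p = 0.531 with an estimated correlation). GFP- replicate 3 read above GFP- replicates 1 and 2 for some genes of these 2 lists, such as Pfkp (922 against 627 and 600) and Pgk1 (1977 against 1257 and 1642), but not for Aldoa (4734 against 5000 and 4551). No list was tested without that array, a limit shared by every comparison that uses it. Cholesterol synthesis genes had a median of -0.23 (camera adjusted p = 2.46e-04, and adjusted p = 0.402 with an estimated correlation). Mast cell markers had a median of -0.65 (camera adjusted p = 1.36e-05, and adjusted p = 0.443 with an estimated correlation). For some of them GFP+ replicate 1 was at the level of the GFP- arrays, such as Cpa3 (2085 against 2009 to 2686), and for others below it, such as Tpsb2 (94.0 against 128 to 142). ILC2 genes had a median of -0.14 (camera adjusted p = 0.0130, and adjusted p = 0.357 with an estimated correlation). NF-kB genes had a median of -0.27 (camera adjusted p = 0.0210, and adjusted p = 0.402 with an estimated correlation) and keratinocyte markers one of -0.25 (camera adjusted p = 0.0311, and adjusted p = 0.712 with an estimated correlation). T cell markers had a median of 0.20 (camera adjusted p = 0.0311, and adjusted p = 0.402 with an estimated correlation). The B and plasma cell markers had a median of 0.15 (camera adjusted p = 0.0271, and adjusted p = 0.402 with an estimated correlation). Without GFP+ replicate 1, the NF-kB (camera adjusted p = 0.0762), keratinocyte (0.394) and B and plasma cell lists (0.670) did not pass, and the medians were 0.46 for T cell and -1.03 for mast cell markers. Without this array, which carried mast cell transcripts, 7 probe sets passed, and 1 passed without GFP+ replicate 2.

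Whether the gate effect differed between genotypes was tested by the interaction. The limma fit called 0 probe sets (smallest adjusted p = 0.0723), with 2378 at an unadjusted p under 0.05. Plek had a difference of gate effects (Rag1-/- minus Rag1-sufficient) of 2.41 ± 0.24, Nusap1 of -1.38 ± 0.16, the sialic acid receptor Cd33 of 1.30 ± 0.15, Xcr1 of 0.85 ± 0.10 and the mitochondrial ribosome gene Mrpl50 of -1.29 ± 0.16, each with an adjusted p of 0.0723. Without Rag1-/- GFP+ replicate 2, 500 sets passed the interaction, and with array weights 31. Across the 17445 sets the gate effects of the genotypes, which share no arrays, had a correlation of -0.10 (genes are not independent replicates).

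Among CCR10+ ILCs, loss of Rag1 went with far more transcript of the cytotoxic granule protease Gzmc, more Cd3e, the signalling chain of the T cell receptor, and less S1pr1 and Nusap1. Gzmc was at 716 ± 220 (n = 2) in Rag1-/- and 38.3 ± 9.85 (n = 2) in Rag1-sufficient cells, a rise of 4.18 ± 0.30 (adjusted p = 0.00312). The lower mean lies under the filter limit of 41.6 units, so the size of this rise is approximate. Cd3e was at 1372 ± 861 (n = 2) against 195 ± 53.5 (n = 2), a rise of 2.68 ± 0.39 (adjusted p = 0.0419), in cells sorted as CD3-negative. S1pr1, through which lymphocytes leave tissue, was at 84.1 ± 16.4 (n = 2) against 215 ± 56.8 (n = 2) and fell by 1.33 (adjusted p = 0.0320). In all, 43 sets differed, 9 higher and 34 lower in Rag1-/- cells.

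The brightest gain was in a probe set annotated to Kcnma1, a potassium channel gene. It read 8961 ± 319 (n = 2) in Rag1-/- and 36.5 ± 18.8 (n = 2) in Rag1-sufficient GFP+ cells (adjusted p = 2.71e-05). No fold is given, since the lower level lies under the filter limit of 41.6 units. The other probe set annotated to Kcnma1 differed by 0.44 and stayed between 37.8 and 70.2 on all arrays, so the value is given for this probe set and not for the gene. Ptgs2, the inducible cyclooxygenase, rose by 1.58 ± 0.23, the proton pump subunit Atp6v0a1 by 1.10 ± 0.14 and the growth factor signalling inhibitor Spry2 by 0.74 ± 0.09. Clec12a fell by 1.68, the matrix metalloproteinase Mmp10 by 1.09 and the lipid transporter Mfsd2a by 1.08.

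Of the 24 cell cycle genes all were lower in Rag1-/- CCR10+ cells, with a median of -0.49, and 1 fell, or 12 when adjusted over the list alone (camera adjusted p = 4.48e-15, and adjusted p = 0.270 with an estimated correlation). Nusap1 fell by 1.19 ± 0.12 (adjusted p = 0.0162), the mitotic genes Cdca3 by 0.64 and Kif18b by 0.62, and the histone genes H2bc14 by 1.29 and H2ac4 by 1.14. Histone sets made up 18 of the 34 lower sets. Nusap1, Clec12a and these histone genes were also among those higher in Rag1-sufficient CCR10+ than CCR10- cells, and both comparisons use the same 2 Rag1-sufficient GFP+ arrays, so their values are not independent.

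MHC class II genes were lower as a group, while the MHC class I list did not pass (camera adjusted p = 0.831). The 11 MHC class II genes had a median of -0.55, or -0.25 without Rag1-/- GFP+ replicate 1, none passed over all genes (1190 sets had an unadjusted p under 0.05 in limma) and 5 fell when adjusted over the list alone (camera adjusted p = 1.21e-07, and adjusted p = 0.330 with an estimated correlation). The costimulatory ligand Cd80 differed by -2.10 ± 0.37 (adjusted p = 0.0894) and the class II chain H2-Aa by -1.92 ± 0.47 (adjusted p = 0.285). T cell markers had a median of 0.66, with 1 rising, or 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00140, and adjusted p = 0.270 with an estimated correlation). NK and ILC1 genes, which include Gzmc, had a median of 0.35 (camera adjusted p = 0.0110, and adjusted p = 0.517 with an estimated correlation), and the chemokine Xcl1 of that list differed by 2.68 ± 0.58 (adjusted p = 0.201). ILC3 genes had a median of 0.14 (camera adjusted p = 0.0354, and adjusted p = 0.502 with an estimated correlation). Migration genes had a median of -0.14 (camera adjusted p = 0.0278, and adjusted p = 0.517 with an estimated correlation), with Ccr4 at -1.43 ± 0.23 (adjusted p = 0.0655). Cholesterol synthesis genes had a median of -0.20 (camera adjusted p = 0.0110, and adjusted p = 0.502 with an estimated correlation) and keratinocyte markers one of -0.65 (camera adjusted p = 8.61e-05, and adjusted p = 0.502 with an estimated correlation). Mast cell markers were higher, with a median of 0.35 (camera adjusted p = 9.94e-05, and adjusted p = 0.502 with an estimated correlation). That direction rested on Rag1-/- GFP+ replicate 1, without which the mast cell list pointed down (camera adjusted p = 0.378). Without this array the migration list had a median of 0.04 (camera adjusted p = 0.912) and the cholesterol list one of -0.12 (0.151). The medians were then 0.61 for NK and ILC1, 1.02 for T cell and 0.24 for ILC3 genes.

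The count of 43 changed strongly with single arrays: it was 3 without GFP+ replicate 1, 1 without GFP+ replicate 2, and 2 without either GFP- replicate of the Rag1-sufficient arrays. Leaving out Rag1-/- arrays gave 9 without GFP+ replicate 1, 135 without GFP+ replicate 2 and 3 without GFP- replicate 2. A fit on only the 4 arrays compared called 0 sets (788 at an unadjusted p under 0.05 in limma), and quantile normalization called 17 (7 higher and 10 lower). The Kcnma1-annotated set passed in 15 of 15 alternatives and Gzmc in 14 of 15, with an adjusted p of 0.0735 without Rag1-sufficient GFP+ replicate 2. The other named genes of this comparison passed less often: Nusap1 and Spry2 in 8 of 15, Cd3e in 5 of 15, S1pr1 and Ptgs2 in 3 of 15, Cdca3 in 2 of 15, and Clec12a and Kif18b in 1 of 14.

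Among sorted CCR10- cells, loss of Rag1 again went with more signal of Gzmc and of the same Kcnma1-annotated probe set. Single genes such as Il1b, Plek and Cd33 were lower, and the cells these transcripts came from were not resolved. Gzmc was at 907 ± 250 (n = 3) in Rag1-/- and 87.6 ± 1.36 (n = 2) in Rag1-sufficient cells, 9.99-fold higher (3.32 ± 0.27, adjusted p = 0.00972). The Kcnma1-annotated set read 9671 ± 194 (n = 3) against 33.2 ± 5.13 (n = 2), and rose (adjusted p = 1.06e-05). Il1b was at 77.9 ± 21.8 (n = 3) against 406 ± 47.1 (n = 2) and fell by 2.40 (adjusted p = 0.0246). In all, 25 sets differed, 9 higher and 16 lower.

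The pyrimidine salvage enzyme Upp1 rose by 1.46 ± 0.17 and acid sphingomyelinase, Smpd1, by 1.33 ± 0.16. Prelid2 rose by 1.56 ± 0.19 and the adhesion receptor Adgrg1 by 1.11 ± 0.15. Among those that fell were Plek by 1.48, Csf2rb, a receptor chain shared by GM-CSF and related cytokines, from 153 to 66.0 units, Cd33 by 1.12 and the lectin Clec10a by 1.05. Lrrn1 fell by 1.27, Pdk4, which restrains pyruvate oxidation, by 1.23, the kinases Lrrk2 by 1.03 and Dapk1 by 0.80, and the endosomal GTPase Rab7b by 0.82. Plek and Il1b were also among the genes lower in Rag1-sufficient CCR10+ cells, a comparison that uses the same 2 Rag1-sufficient GFP- arrays.

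Glycolysis genes were all higher in Rag1-/- CCR10- cells, with a median of 0.35, and 5 rose when adjusted over the list alone, none over all genes (camera adjusted p = 1.10e-05, and adjusted p = 0.332 with an estimated correlation). In this limma fit 3014 sets had an unadjusted p under 0.05. All 18 oxidative phosphorylation genes were higher, with a median of 0.45 (camera adjusted p = 4.76e-06, and adjusted p = 0.356 with an estimated correlation). Rag1-/- GFP- replicate 3 stood above replicates 1 and 2 for some of them, such as Atp5a1 (1397 against 691 and 832) and Cox4i1 (489 against 259 and 334), but not for Cycs (4578 against 4469 and 4819). Neither of these 2 lists was tested without that array. MHC class II genes had a median of -0.44, with 6 lower and 2 higher when adjusted over the list alone (camera adjusted p = 9.31e-04, and adjusted p = 0.342 with an estimated correlation). H2-Ab1 differed by -1.48 ± 0.22 (adjusted p = 0.0525) and H2-Eb1 by -1.45 ± 0.21 (adjusted p = 0.0520), both chains of class II molecules. MHC class I genes had a median of 0.40 (camera adjusted p = 0.0150, and adjusted p = 0.332 with an estimated correlation). Cd3e differed by 1.78 ± 0.36 (adjusted p = 0.101). The NF-kB list (camera adjusted p = 0.120) and the receptor list (0.306) did not pass.

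Markers of other cells moved along in this comparison. Mast cell markers had a median of -1.13, with 8 lower when adjusted over the list alone (camera adjusted p = 2.79e-08, and adjusted p = 0.332 with an estimated correlation). Keratinocyte markers had a median of -0.86, with 9 lower when adjusted over the list alone (camera adjusted p = 3.04e-07, and adjusted p = 0.332 with an estimated correlation). Without Rag1-sufficient GFP- replicate 2 their median was -0.53 (camera adjusted p = 6.81e-04). Krt14 was at 180 ± 95.7 (n = 3) in Rag1-/- and 579 ± 287 (n = 2) in Rag1-sufficient GFP- cells (adjusted p = 0.159). Immediate early genes had a median of -0.26 (camera adjusted p = 4.13e-04, and adjusted p = 0.332 with an estimated correlation). Endothelial markers had a median of -0.43 (camera adjusted p = 0.00381), macrophage and monocyte markers one of -0.28 (0.00522) and fibroblast markers one of -0.24 (0.0111), each with an adjusted p of 0.332 with an estimated correlation. The B and plasma cell markers had a median of -0.19 (camera adjusted p = 0.0431, and adjusted p = 0.346 with an estimated correlation). Without Rag1-sufficient GFP- replicate 2 neither these (0.0579) nor the fibroblast markers (0.133) passed.

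The count of 25 was 9 without GFP- replicate 1 and 1 without GFP- replicate 2 of the Rag1-sufficient arrays. Among Rag1-/- arrays it was 78 without GFP+ replicate 1 and 76 without GFP+ replicate 2. It was 139 without GFP- replicate 1, 2 without GFP- replicate 2 and 4 without GFP- replicate 3. Array weights gave 1168 sets, a pseudocount of 32 gave 46, a filter at 50% gave 9 and the fit on only the groups compared gave 8.

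**Figure D2:**
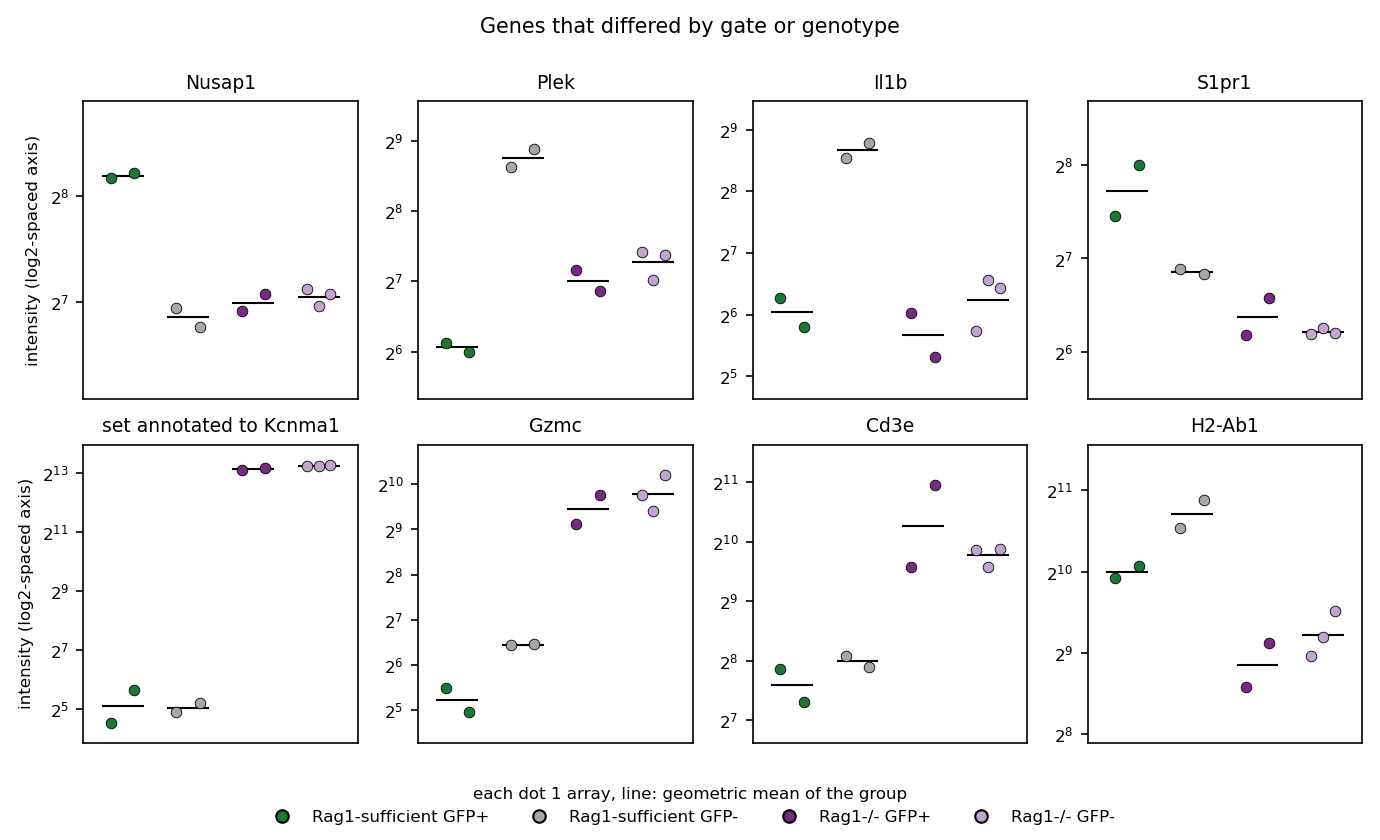
Array intensities (log2-spaced axis) of 8 probe sets by fraction and genotype, 1 dot per array with a line at the geometric mean of the group. The set annotated to Kcnma1 lies between 8736 and 9891 on the 5 Rag1-/- arrays and between 23.2 and 49.8 on the 4 Rag1-sufficient arrays, and Gzmc between 560 and 1173 against 31.3 to 88.6.

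Averaged over fractions, Rag1-/- cells read higher than Rag1-sufficient cells for Gzmc, Cd3e and the Kcnma1-annotated probe set. They read lower for the class II gene H2-Ab1 and the egress receptor S1pr1. Gzmc rose by 3.75 ± 0.20 (adjusted p = 3.00e-04), Cd3e by 2.23 ± 0.27 (4.69-fold, adjusted p = 0.0410) and the Kcnma1-annotated set rose as well (adjusted p = 9.06e-07). H2-Ab1 fell by 1.32 (adjusted p = 0.0466) and S1pr1 by 0.98 (adjusted p = 0.0466). In all 15 sets differed, 10 higher and 5 lower. Upp1 rose by 1.19, Amph, an endocytosis protein, by 1.28, the metalloproteinase inhibitor Timp2 by 0.91 and the collagen-modifying enzyme Colgalt2 by 0.78. Lrrn1 fell by 0.85, Mmp10 by 0.78 and Lrrk2 by 0.59, while a second and dimmer Lrrk2 set differed by -0.10. The 2 fractions, which share no arrays, had 5 higher sets in common (0.00464 by chance for independent lists) and 0 lower ones (0.0312 by chance). This was out of 9 and 9 higher and 34 and 16 lower calls in limma. Both tests used the same spread per probe set, estimated from all arrays. The lists are therefore not independent, and the chance values do not strictly apply. Across all sets the genotype effects of the fractions had a correlation of -0.02, and 11 of the 43 sets called in GFP+ cells had the same sign in GFP- cells.

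Class II genes were lower in Rag1-/- cells averaged over fractions: 1 fell over all genes, and 8 fell and 1 rose when adjusted over the list alone (median -0.40, camera adjusted p = 6.98e-08, and adjusted p = 0.274 with an estimated correlation). T cell markers had a median of 0.62, with 1 rising over all genes and 6 rising and 2 falling over the list alone (camera adjusted p = 0.00361, and adjusted p = 0.274 with an estimated correlation). Cd3g differed by 1.28 ± 0.24 (adjusted p = 0.0878) and the costimulatory receptor Cd28 by -1.13 ± 0.24 (adjusted p = 0.130). NK and ILC1 genes had a median of 0.34, with 1 rising over all genes and 6 rising and 2 falling over the list alone (camera adjusted p = 0.00322, and adjusted p = 0.460 with an estimated correlation). Xcl1 differed by 2.21 ± 0.39 (adjusted p = 0.0815) and Ccl5 by -1.31 ± 0.25 (adjusted p = 0.0893). ILC3 genes had a median of 0.23 (camera adjusted p = 0.0112, and adjusted p = 0.274 with an estimated correlation; median 0.14 without Rag1-sufficient GFP- replicate 2), with the chemokine receptor Ccr6 at 0.75 ± 0.11 (adjusted p = 0.0606).

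Keratinocyte markers were lower in Rag1-/- samples, with a median of -0.93 and 11 of 13 lower when adjusted over the list alone (camera adjusted p = 4.77e-10, and adjusted p = 0.274 with an estimated correlation). Cell cycle genes had a median of -0.19 (camera adjusted p = 1.11e-05, and adjusted p = 0.274 with an estimated correlation) and macrophage markers one of -0.14 (camera adjusted p = 0.00284, and adjusted p = 0.274 with an estimated correlation). Glycolysis genes had a median of 0.17 (camera adjusted p = 1.20e-04, and adjusted p = 0.274 with an estimated correlation). Mast cell markers had a median of -0.38 (camera adjusted p = 0.0105, and adjusted p = 0.478 with an estimated correlation). Pan-ILC genes had a median of 0.08, melanocyte and Schwann cell markers one of -0.25 and fibroblast markers one of -0.13, each with a camera adjusted p of 0.0420 (adjusted p = 0.410 with an estimated correlation). Without Rag1-sufficient GFP- replicate 2 none of these 3 lists passed (0.0563, 0.0787 and 0.254). Without Rag1-/- GFP+ replicate 1 the melanocyte (0.110) and fibroblast lists (0.327) did not pass, and the medians were -0.67 for mast cell, 0.60 for NK and ILC1 and 0.16 for pan-ILC genes. No cytokine or regulator of the fixed panel passed: Il5 differed by -0.52 ± 0.18 (adjusted p = 0.373), Tbx21 by 0.53 ± 0.22 (0.484) and Ifng by -0.36 ± 0.47 (0.857). Without Rag1-/- GFP+ replicate 1 Tbx21 differed by 0.84 (adjusted p = 0.0251) and Ifng by 0.27. Gata3 differed by 0.06 ± 0.15, Il13 by -0.07 ± 0.13, Il7r by -0.08 ± 0.12 and Id2 by -0.02 ± 0.06, with adjusted p between 0.886 and 0.929. Without Rag1-/- GFP+ replicate 1 each of these 4 turned direction (Gata3 -0.09, Il13 0.08, Il7r 0.02 and Id2 0.03).

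The count of 15 was 2 without Rag1-sufficient GFP+ replicate 2, 5 without GFP- replicate 1 and 2 without GFP- replicate 2. It was 64 without Rag1-/- GFP+ replicate 1, 33 without GFP+ replicate 2, 4 without GFP- replicate 2 and 6 without GFP- replicate 3. Quantile normalization gave 33 sets (16 higher and 17 lower) and array weights 64. No filter gave 5 higher and 0 lower sets, so the decreases of H2-Ab1 and S1pr1 did not pass there. The Kcnma1-annotated set and Gzmc passed in 15 of 15 alternatives. H2-Ab1 passed in 7 of 15, and Cd3e and S1pr1 each in 6 of 15.

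Averaged over genotypes, sorted CCR10+ cells had lower levels of Plek and of mast cell genes such as Tpsb2 and Mrgprb1 than CCR10- cells. The inflammatory genes Il1b and Cxcl2 were lower as well. Since the GFP- arrays carried mast cell transcripts, whether ILCs or other sorted cells account for the differences of this comparison was not resolved. Of 37 sets that differed 34 were lower and 3 higher in GFP+ cells. Plek fell by 1.47 (adjusted p = 0.00797), Tpsb2 by 1.27, Mrgprb1 by 2.14, Cma1 by 1.69 and Cyp11a1 by 1.48. Il1b fell by 1.58, Cxcl2 by 1.32 and Jun by 0.81, the receptors Lilr4b by 1.77, Gpr141b by 1.64, Pilra by 1.58 and the melanocortin receptor Mc5r by 1.64, and Snora75 (-2.22) fell as well. Nusap1 was the one named gene that rose, by 0.64 ± 0.08 (adjusted p = 0.0318). For several of these genes the fractions overlapped in Rag1-/- mice, so the average rests on Rag1-sufficient mice. There Nusap1 read 121 and 135 in Rag1-/- GFP+ against 124 to 139 in Rag1-/- GFP- arrays, Plek 142 and 116 against 130 to 170, and Il1b 65.5 and 39.6 against 53.1 to 94.1. Tpsb2 did not overlap, at 94.0 and 65.4 against 128 to 142.

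The NF-kB list, with 2 genes lower over all genes and 5 over the list alone, passed with the preset (camera adjusted p = 2.51e-08) and with an estimated correlation (adjusted p = 0.0434). The same held for the ILC2 list, with none lower over all genes (1287 sets at an unadjusted p under 0.05 in limma) and 7 over the list alone (camera adjusted p = 3.68e-07, and adjusted p = 0.0434 with an estimated correlation). Within it Klrg1 differed by -1.14 ± 0.18 (adjusted p = 0.0646), the growth factor Csf2 by -0.75 ± 0.14 (adjusted p = 0.0967) and the lipid regulator Pparg by -0.47 ± 0.09 (adjusted p = 0.0977). The mast cell list had a camera adjusted p of 9.77e-26 (adjusted p = 0.0850 with an estimated correlation), which with an estimated correlation passed without Rag1-/- GFP+ replicate 1 (0.0264) and not without Rag1-sufficient GFP- replicate 2 (0.153). The immediate early list had one of 1.58e-07 (adjusted p = 0.0850 with an estimated correlation) and the cell cycle list, which was higher, one of 3.68e-07 (adjusted p = 0.230 with an estimated correlation), with a median of 0.17, or 0.27 without Rag1-/- GFP+ replicate 1. With all arrays, NF-kB and ILC2 in this average were the 2 list calls of any comparison that also passed with an estimated correlation, and without Rag1-/- GFP+ replicate 1 both had an adjusted p of 0.133 in that test. Without Rag1-sufficient GFP- replicate 2 it was 0.0814 for ILC2 and 0.0914 for NF-kB genes.

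Other lists moved in this average as well. Keratinocyte markers had a median of -0.46 (camera adjusted p = 9.00e-07, and adjusted p = 0.301 with an estimated correlation), or -0.22 without Rag1-sufficient GFP- replicate 2. Dendritic and Langerhans cell markers had one of -0.20 (camera adjusted p = 0.00247, and adjusted p = 0.108 with an estimated correlation), or -0.06 without Rag1-/- GFP+ replicate 1. T cell markers had one of 0.18 (camera adjusted p = 0.0454, and adjusted p = 0.301 with an estimated correlation), or 0.35 without Rag1-/- GFP+ replicate 1. Glycolysis genes had one of -0.19 (camera adjusted p = 0.00115, and adjusted p = 0.301 with an estimated correlation). The fatty acid list (camera adjusted p = 0.0151, and adjusted p = 0.374 with an estimated correlation) and the cholesterol list (camera adjusted p = 0.0244, and adjusted p = 0.412 with an estimated correlation) were lower. Without Rag1-/- GFP+ replicate 1 (0.0827 and 0.208) or Rag1-sufficient GFP- replicate 2 (0.0813 and 0.0638) neither passed.

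The count of 37 fell to 0 without Rag1-sufficient GFP+ replicate 1, GFP+ replicate 2 or GFP- replicate 2, with 965, 1002 and 746 sets at an unadjusted p under 0.05 in limma, and to 5 without GFP- replicate 1. It was 136 without Rag1-/- GFP+ replicate 1, 8 without GFP- replicate 1, 6 without GFP- replicate 2 and 7 without GFP- replicate 3. The other splits of the arrays within genotypes gave as many sets or more in 3 of 60 cases, the real one included.

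**Figure D3:**
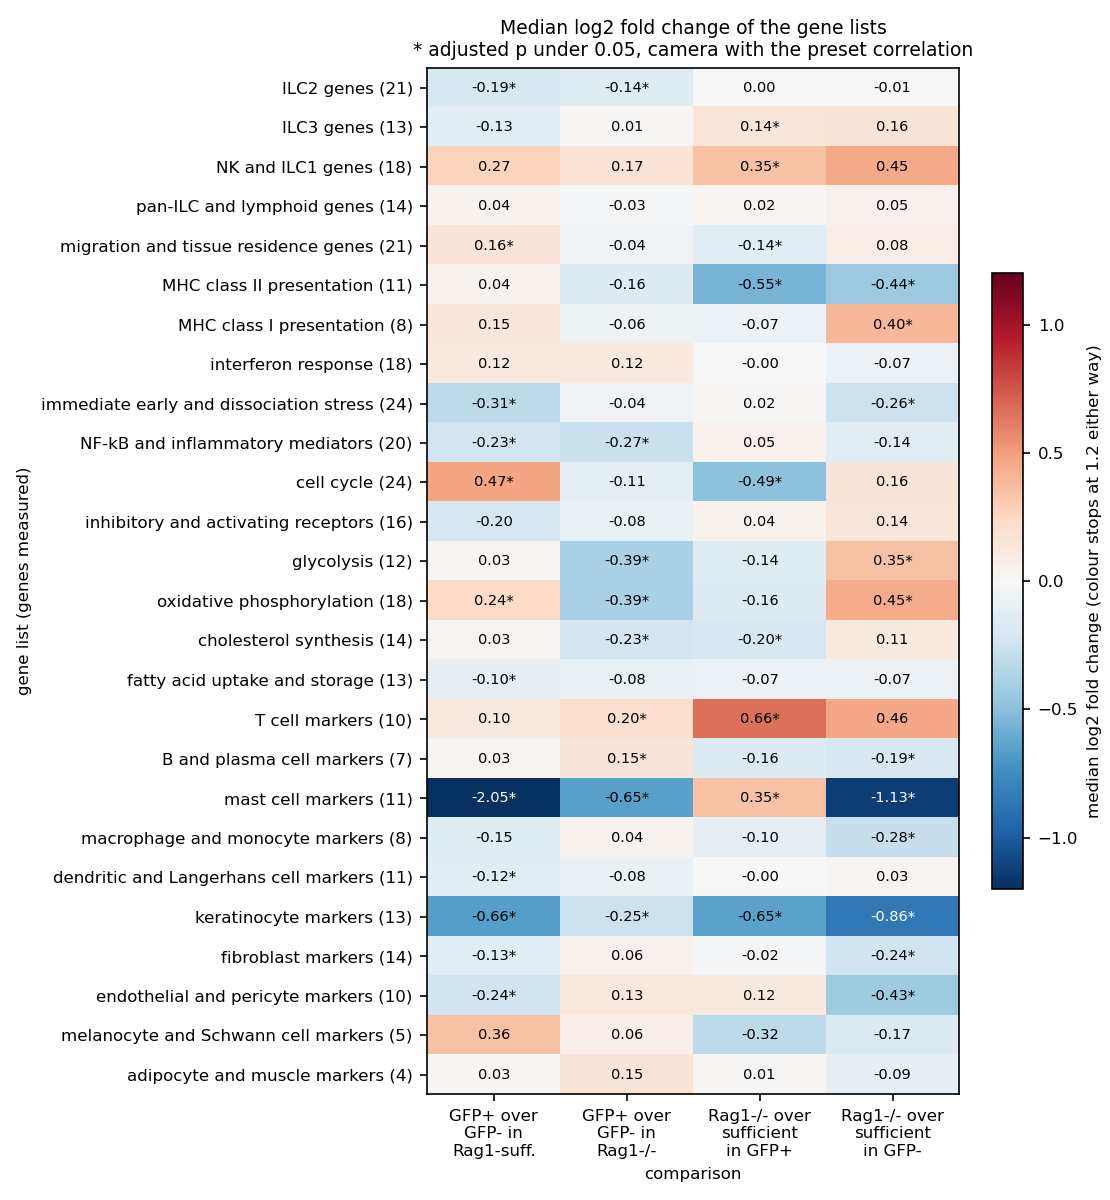
Median log2 fold change of the 26 tested gene lists (vertical axis, number of genes measured in brackets) in the 4 comparisons between pairs of groups (horizontal axis), with colour for the direction and an asterisk for a camera adjusted p under 0.05 at the preset correlation. Mast cell markers read -2.05 for the gate in Rag1-sufficient mice and -1.13 for the genotype in GFP- cells, and no asterisk of these comparisons holds with an estimated correlation.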

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

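The list tests without Rag1-/- GFP+ replicate 1 and the tests of a wrong label, of single-gene regulation, of the second Kcnma1 set and of the set next to it were chosen only after the results were seen.

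The 7 gene lists named here were singled out because their gate effect (GFP+ minus GFP-) differed between genotypes in a camera test of the interaction. The mast cell list had an adjusted p of 1.88e-11 (adjusted p = 0.393 with an estimated correlation), with a gate effect less negative in Rag1-/- mice for all 11 genes (median difference 1.55, or 0.98 without Rag1-/- GFP+ replicate 1). Immediate early genes (adjusted p = 0.00039, and adjusted p = 0.393 with an estimated correlation) and endothelial and pericyte markers (0.00311, and adjusted p = 0.411 with an estimated correlation) moved the same way. The cell cycle list differed in the other direction, with all 24 genes less favoured in Rag1-/- CCR10+ cells and a median difference of -0.68 (adjusted p = 1.91e-09, and adjusted p = 0.393 with an estimated correlation). Oxidative phosphorylation genes (adjusted p = 1.29e-05, and adjusted p = 0.448 with an estimated correlation), glycolysis genes (0.00316, and adjusted p = 0.420 with an estimated correlation) and cholesterol synthesis genes (0.0315, and adjusted p = 0.496 with an estimated correlation) also had negative differences, and without Rag1-/- GFP+ replicate 1 the cholesterol list did not pass (0.0766).

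Mast cell transcripts were present in all 5 GFP- arrays and in Rag1-/- GFP+ replicate 1, and low in the other 3 GFP+ arrays: Cpa3 read 2009 to 4965 against 19.9 to 21.5. All 11 of the 11 measured mast cell genes were higher in Rag1-/- GFP+ replicate 1 than in replicate 2, but they are co-expressed (estimated correlation 0.708) and count as about 1 independent gene. That correlation was estimated from the same arrays, the difference between these 2 replicates included. The count therefore cannot decide, and regulation of these genes without mast cells stays open. Mast cells among the sorted cells stay open as well. The sort excluded no mast cell marker, while Kit and Gata2 of that list are also ILC genes. The 74 other sets lower in Rag1-sufficient CCR10+ cells were higher in replicate 1 by a median of 0.13 (0.0874 to 0.242). The median over all tested sets was -0.016, and 57 of the 74 sets were higher in replicate 1. The shift is short of what was set for either answer, and its interval treats co-expressed sets as independent. A wrong label of replicate 1 cannot be told apart either, since the 58 sets higher in Rag1-sufficient CCR10+ cells averaged 9.46 (log2) in it and 9.62 in replicate 2, against 9.59 to 9.65 in the Rag1-/- GFP- arrays, and a true difference between the animals was not tested.

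The probe set annotated to Kcnma1 read 8736 to 9891 in the Rag1-/- and 23.2 to 49.8 in the Rag1-sufficient arrays. A change of the Kcnma1 gene stays open: its other probe set had an upper 95% bound of 0.651 for the difference, but it reads 37.8 to 70.2, near the filter limit of 41.6, where a change can be understated. The next probe set in identifier order, which has no gene name, rose by 1.22 (adjusted p = 0.00808), while 0 of the 16 nearest named sets, all of genes on chromosome 8 such as Fanca and Dbndd1, passed in limma, in a fit with 1717 sets at an unadjusted p under 0.05. This is consistent with a transcript from another locus than Kcnma1. As a hypothesis that no value here tests, the ecotropic leukaemia provirus that B6 mice carry on chromosome 8, which has been described as active in mice without adaptive immunity, is a candidate source. Aligning the probe sequences, which were not available, would decide it.

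The number of sets that differed between genotypes in both fractions together was higher than in any other split of the arrays: 1 of 60 splits within fractions, the real one, gave as many as 15 sets, and the highest other split gave 4. This covers the count and not each gene in it, and 60 splits allow no smaller share than 1 of 60. A chromosome segment carried along with the Rag1 mutation from the strain in which it was made may account for part of the 15 sets. Sets of the 200 tested genes on each side of Rag1 reached an unadjusted p of 0.01 in 23 of 419 cases, against 465 of 14662 elsewhere (odds ratio 1.77, 95% interval 1.10 to 2.73, Fisher's exact test p = 0.0160). Of these 419 sets 1 was among the 15 called, so the segment leaves most of the calls unaccounted for, and an effect of missing T and B cells stays open as the design's own explanation.

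For the gate effect averaged over genotypes (37 sets) the splits cannot decide in the same way: 3 of 60 splits within genotypes gave as many sets or more, and the highest other split gave 263. That split exchanged both Rag1-sufficient fractions, which keeps their gate difference whole with its sign reversed. It also grouped Rag1-/- GFP+ replicate 1 with GFP- replicate 1 and the Rag1-sufficient GFP- arrays. Its count is therefore no measure of chance, which stays open for the 37 sets.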

How the results depend on the processing

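The crossed pairing, the fit without mast cell genes and the list tests without Rag1-/- GFP+ replicate 1 and without Rag1-sufficient GFP- replicate 2 were chosen after seeing the data.

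Named genes past the threshold kept their direction under the alternatives run, while some that did not pass turned, such as Ccr10 for the gate in Rag1-/- mice. The counts depend on single arrays. Leaving out each array in turn gave 3 to 335 sets for the gate in Rag1-sufficient mice (140 with all arrays), 0 to 7 for the gate in Rag1-/- mice (0), 1 to 135 for the genotype in GFP+ cells (43) and 1 to 139 in GFP- cells (25). It gave 0 to 136 for the gate averaged over genotypes (37), 2 to 64 for the genotype averaged over fractions (15) and 0 to 500 for the interaction (0). Leaving out an array of a pair leaves a lone array that is assumed to vary like the other groups.

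For the genotype in GFP+ cells, quantile normalization gave 17 sets, only the groups compared 0 (788 at an unadjusted p under 0.05 in limma) and the replicate block 2. For the genotype in GFP- cells, a filter at 50% gave 9, a pseudocount of 32 gave 46, only the groups compared 8, array weights 1168 and the replicate block 6. For the genotype averaged over fractions, no filter gave 5, quantile normalization 33, array weights 64 and the replicate block 9. The gate averaged over genotypes gave 23 with the replicate block, the gate in Rag1-sufficient mice 1290 with array weights, and the interaction 1 with a filter at 50%, 1 with quantile normalization and 31 with array weights. A filter at 50% tests fewer sets; for the other settings the cause was not tested. The gate in Rag1-/- mice called 0 sets in limma with each setting that kept all its arrays, with 453 to 1486 at an unadjusted p under 0.05.

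Whether equal replicate numbers pair the arrays could not be decided. Their deviations from the group means correlated at 0.08 across gates in Rag1-sufficient mice, and at 0.03 and -0.24 in Rag1-/- mice. Across genotypes the values were -0.11, -0.16 and 0.01. In a group of 2 arrays the deviations mirror each other, so such values cannot show whether equal numbers share animals. With the crossed pairing the genotype in GFP+ cells called 2 sets. Without the mast cell list and every set more than 2-fold higher in Rag1-/- GFP+ replicate 1 than in replicate 2, the gate in Rag1-sufficient mice called 119 sets, each of them among the 140. Sets that moved the same way by less stayed in, such as Lilr4b (202 against 105), so the 119 sets are not free of mast cell signal.

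Of the list calls, 2 remained and 71 were lost with an estimated correlation, 13 remained and 60 were lost in fry, 57 and 16 with quantile normalization, 66 and 7 with the replicate block, 60 and 13 without Rag1-/- GFP+ replicate 1, and 61 and 12 without Rag1-sufficient GFP- replicate 2. Signal over background limits what can be read: genes under an intensity of 41.6, Rag1 and Rag2 among them, were not tested, and differences of tested genes with a group near that limit are approximate.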

Other observations

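The test described here was chosen after seeing the data.

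The 2 Rag1-/- GFP+ samples differed in more than mast cell genes. Replicate 2 had the highest levels of some cytotoxic and type 1 lymphocyte genes among the 5 Rag1-/- arrays, but not of Gzmc (872, against 1173 in GFP- replicate 3). The genes given here were chosen for this pattern. Xcl1, a chemokine of NK cells and ILC1, read 1901 against 457 in replicate 1 and 573 to 907 in the GFP- arrays. Ifng read 553 against 95.4 in replicate 1 and 149 to 218 in the GFP- arrays, Tbx21 661 against 283, and the pore-forming protein Prf1 258 against 142. Cd3e read 1981 in replicate 2 and 763 in replicate 1.

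With replicate 1 left out, CCR10+ ILCs of Rag1-/- mice had higher NK and ILC1 genes than CCR10- ILCs, with a median of 0.94 and 16 of 18 genes higher (camera adjusted p = 3.59e-16, and adjusted p = 0.103 with an estimated correlation). T cell markers had a median of 0.46 (camera adjusted p = 4.96e-06, and adjusted p = 0.178 with an estimated correlation). The mast cell markers then had a median of -1.03, with all 11 genes lower (camera adjusted p = 7.08e-27, and adjusted p = 0.0403 with an estimated correlation). These values rest on a single CCR10+ array and describe that sample.

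Tnfrsf4 read 987 to 1647 in the 3 Rag1-/- GFP- arrays, above the other 6 arrays at 320 to 632. On the principal components, of which the first held 36.1% and the second 19.6% of the variance, Rag1-/- GFP- replicate 3 lay farthest out on the first (-36.5), and Rag1-/- GFP+ replicate 1 (18.2) lay near the Rag1-sufficient GFP- arrays (21.0 and 25.0) while replicate 2 lay at -8.23.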
